A study of Homo sapiens with 6 samples.

How the data were processed

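RNA was sequenced from A-375 cells, an established human melanoma line, in 6 libraries: 3 carrying a control guide and 3 carrying a guide against SEPHS2. Groups and replicate numbers were taken from the sample titles. The sources used here do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

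The authors deposited 1 table of raw read counts per gene symbol, with no normalization, which summed to a different total in each library. Per the submitters' processing notes, FastQC 0.12.1, HISAT2 2.2.1, SAMtools 1.21 and featureCounts 2.0.6 from the Subread package were used with genome build GRCh38. The gene annotation, strand setting, treatment of reads that map to several places and any filter on genes are not given in the sources used here. The table held 21631 symbols, and the smallest total of any gene over the 6 libraries was 7 reads. Of these symbols, 21119 matched RefSeq genes on GRCh38.p14, which supplied positions and gene types. The counts of 1108 genes, 530 of them tested, were identical to those of another symbol, and such genes are treated as uncertain. Genes with close paralogs or processed pseudogenes, among them ALPP, KRT81, HLA-B, FTL, HSP90AA1, HSPA8, RPSA, GAPDH and HNRNPA1, are also uncertain. The same holds for overlapping and antisense genes, since the strand setting is not known.

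Depth ranged from 34606145 to 43405579 counted reads per library. Genes were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors, the default expression filter with the group, and the quasi-likelihood test, which is two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 16910 genes tested, and 4721 genes were left out by the filter. A single-gene adjusted p comes from this test unless an alternative is named beside it, such as DESeq2 or a refit with 1 library left out, and every log2 fold change is the libraries labelled knockout over control. CPM values used TMM-scaled library sizes and are given as mean ± SD of 3 libraries. For genes with few reads in one group, ratios carry exact 95% conditional binomial intervals. A group with no reads was set to 3 reads over the group, which gives a nominal bound. Both cover counting error only, because reads without molecular identifiers are not independent molecules.

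Before the data were examined, 37 gene lists were fixed: 6 primary lists for selenium biology and glucose metabolism, 26 secondary lists, and 5 lists of markers of other cell types. The lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 35 lists with at least 5 tested members. The set test was repeated with an estimated correlation and with fry, which tests only whether a list's genes move, on balance, one way. Counts of list members past the threshold are given over all genes tested and again adjusted over the list alone.

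The rule for named genes was also fixed before the data were examined. It takes SEPHS2 and PCK1, and the 10 largest rises and 10 largest falls among changed genes with a mean of at least 1 CPM, groups that did not overlap and a symbol that is not of a LOC, LINC, clone, antisense or pseudogene type. It adds members of the primary lists, and up to 4 members of each other list by smallest adjusted p, or the most abundant member where none passed. The closing section may add up to 10 abundant changed genes in each direction.

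Alternatives fixed in advance were RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, and an adjusted p under 0.01. Leaving out chromosomes 13 and 18, keeping 1 of each set of genes with identical counts, and removing a smooth trend in exon length and GC content were added after the data were seen. Length and GC content were available for 90.5% of the tested genes. The analysis by position took 12773 genes with a position and at least 2 CPM, running medians of 41 genes, 1000 shuffles of gene positions for chromosomes and 200 for windows. Y-linked genes and XIST, and some members of the fixed lists, are not reported here by name.

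The procedure was tested on simulated counts for this comparison, 3 against 3, over 16910 genes of which 200 were changed. It recovered 32% of the genes changed 1.2-fold, 70% at 1.5-fold, 88% at 2-fold and 96% at 4-fold. It made 7 false calls, 4.67% of all calls, and gave no changed gene the wrong sign. A further simulation changed 455, 550 and 495 genes of the lowest, middle and highest expression class 1.2-fold, so its recovery is not comparable with these values. Both simulations changed a far smaller share of genes than the 45.4% called in the data. The Benjamini-Hochberg threshold loosens as more genes change, so recovery in the data may be higher than in either. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.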

Results

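Gene expression was measured by RNA sequencing in A-375 cells, an established human melanoma line, with a control guide or a guide against SEPHS2. SEPHS2 makes the selenophosphate needed to build selenocysteine. There were 3 libraries per group. The control libraries held 41757643, 41288628 and 39796984 counted reads, and the libraries labelled SEPHS2 knockout held 34606145, 43405579 and 40284730. The comparison asks how gene expression differs in A-375 cells labelled as lacking SEPHS2, and the series title points to glucose metabolism, the pentose phosphate pathway and PCK1. The labels name no separate knockout lines. For every gene and list, a difference in founding cells between the groups therefore cannot be told apart from an effect of SEPHS2 loss.

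The targeted gene was read first, as a check on the labels. SEPHS2 (chromosome 16, 30443631 to 30445874, GRCh38.p14, protein-coding) was not lower in the libraries labelled SEPHS2 knockout. Its level went from 156 ± 3.32 to 173 ± 3.85 CPM (SD, n = 3 per group), a log2 fold change of 0.15, SE 0.04 (edgeR adjusted p = 0.00401). The 3 control libraries held 6671, 6277 and 6269 SEPHS2 reads, and the 3 libraries labelled knockout 5802, 7643 and 6978. A gene-level count covers the whole transcript and does not show whether a guide changed the reading frame. Every direction given for this comparison therefore rests on the labels, and the group is called the libraries labelled knockout.

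In the libraries labelled knockout, PCK1 mRNA, which encodes the cytosolic enzyme of gluconeogenesis that makes phosphoenolpyruvate, was nearly absent. Of the S phase genes 28 of 29 rose, of the mitotic genes 30 of 30, and of the NRF2 target genes 19 of 25, such as FTL and GCLM. Of the inflammatory genes 21 of 25 fell, such as CXCL8 and ICAM1, and of the matrix genes 28 of 44, such as TNC and FN1. Of the pentose phosphate pathway genes 8 of 13 rose modestly, from 1.14-fold for PGLS to 1.36-fold for PRPS2. These 6 lists passed camera with its preset correlation, and had adjusted p = 0.171 to 0.314 with an estimated correlation. Of 16910 genes tested with edgeR, 7673 (45.4%) passed, 3723 higher and 3950 lower. Changes of at least 2-fold were fewer and mostly downward, 211 higher against 959 lower. The groups did not overlap for 8809 genes, 52.1% of those tested, where chance gives 10%. With at least 1 CPM required in 3 libraries, 623 genes changed at least 2-fold, against 1170 in all, so many of these changes were in low genes.

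PCK1 (chromosome 20, 57561110 to 57568121, GRCh38.p14, protein-coding) had 391, 473 and 502 reads in the control libraries and 2 in each library labelled knockout. That is 217 times more in the control group (95% counting interval 99.6 to 593), and a log2 fold change of -7.68, SE 0.25 (edgeR adjusted p = 1.91e-15). PCK2, the mitochondrial form, had 14.8 ± 0.861 CPM in the control group and 14.8 ± 0.862 CPM in the other, with a log2 fold change of 0.01, SE 0.08 (adjusted p = 0.963). Of 10 tested gluconeogenesis genes, 4 fell and 1 rose (1 higher and 4 lower adjusted over the list alone). PC, which makes oxaloacetate from pyruvate, fell from 44 ± 0.823 to 33.5 ± 1.67 CPM (log2 fold change -0.39, edgeR adjusted p = 3.16e-06). The regulators PPARGC1A and FOXO1 fell as well, by log2 fold changes of -1.07 and -1.05, and FOXO1 lies on chromosome 13, whose genes were lower as a whole. SLC37A4 rose by 0.16 (edgeR adjusted p = 0.0171), a call lost without control replicate 2 (adjusted p = 0.0532) or control replicate 3 (adjusted p = 0.0949). The list as a set did not pass camera (adjusted p = 0.098), and its median of -0.06 and mean of -0.98 stand apart, with PCK1 alone at -7.68.

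**Figure D1:**
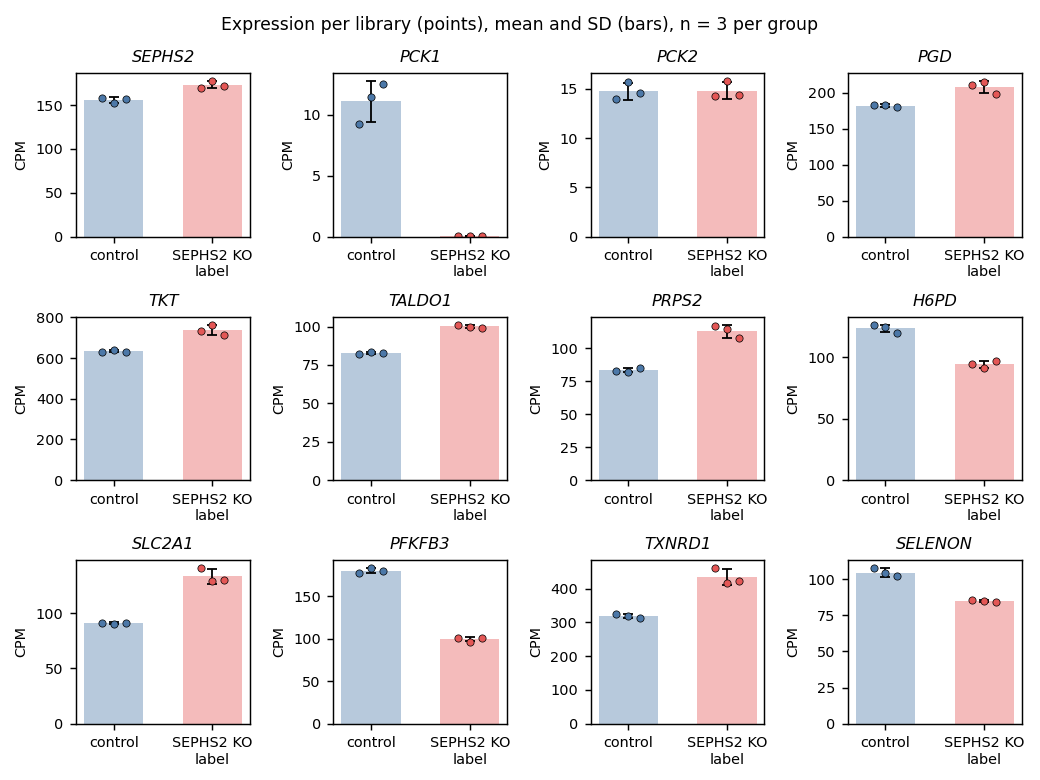
Expression in CPM of 12 genes in the 3 control libraries and the 3 libraries labelled SEPHS2 knockout, with points for libraries, bars for group means and error bars for the SD. PCK1 is near 0 in the libraries labelled knockout, SEPHS2 is slightly higher there, and PGD, TKT, TALDO1 and PRPS2 are higher without overlap.

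Of 13 tested pentose phosphate pathway genes, 8 rose, 1 fell and 4 did not pass (8 higher and 1 lower adjusted over the list alone). PRPS2, which makes phosphoribosyl pyrophosphate, rose from 83 ± 1.52 to 113 ± 4.98 CPM (log2 fold change 0.44, SE 0.04, edgeR adjusted p = 5.65e-08), and its paralog PRPS1 rose by 0.28. TKT and TALDO1, which encode enzymes of the non-oxidative branch, rose by log2 fold changes of 0.22 and 0.27. PGD rose by 0.19 and DERA by 0.31. PGLS rose by 0.19 (edgeR adjusted p = 0.0153), a call lost without control replicate 3 (adjusted p = 0.055) or knockout replicate 2 (adjusted p = 0.12). H6PD, an enzyme of the endoplasmic reticulum, fell from 124 ± 3.19 to 94.3 ± 2.6 CPM (log2 fold change -0.39, edgeR adjusted p = 1.83e-07). The list passed camera with the preset correlation (adjusted p = 0.021, median log2 fold change 0.22), and had adjusted p = 0.314 with an estimated correlation. It also missed the threshold once the length and GC trend was removed (camera adjusted p = 0.0651), with a median log2 fold change of 0.24.

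Glycolysis genes moved in both directions, 14 of 27 higher and 6 lower (14 higher and 6 lower adjusted over the list alone). Without control replicate 1 or control replicate 3 the number higher was 9 in each case, because HKDC1, PFKP, ALDOA, PGK1 and SLC16A3 lost their calls (adjusted p = 0.0546 to 0.17). Without any 1 of the other libraries it was 11 to 13. The number lower was 4 to 7 with 1 library left out, with the calls of SLC2A3, HK1 and ENO2 each lost at least once (adjusted p = 0.0509 to 0.124). The glucose transporter SLC2A1 rose from 91 ± 0.496 to 133 ± 6.47 CPM (log2 fold change 0.55, SE 0.04, edgeR adjusted p = 1.92e-09). ENO1, GAPDH, LDHA and PKM rose by log2 fold changes of 0.38, 0.32, 0.31 and 0.24. PFKFB3, which makes the activator of phosphofructokinase, fell from 180.0 ± 2.74 to 99.4 ± 2.52 CPM (log2 fold change -0.86, SE 0.04, edgeR adjusted p = 5.19e-13), and PFKFB4 fell by -0.33. The list did not pass camera (adjusted p = 0.118), although it did once the length and GC trend was removed (adjusted p = 0.0323). With that trend removed, SLC2A3 and HK1 lost their calls (log2 fold changes -0.07 and -0.06, edgeR adjusted p = 0.157 and 0.156). PFKL, called lower before, had 0.05 (edgeR adjusted p = 0.447).

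Of 29 tested genes that make or use NAD, 8 rose and 5 fell (8 higher and 5 lower adjusted over the list alone). This was no larger a share than the 45.4% of all tested genes that passed. NMNAT2, which makes NAD in the cytoplasm, rose from 12.4 ± 0.261 to 20.4 ± 1.56 CPM (log2 fold change 0.71, SE 0.07, edgeR adjusted p = 6.25e-08). QPRT and KYNU, enzymes of the route from tryptophan, fell by log2 fold changes of -0.85 and -0.54. TDO2, which opens that route, had 1 read over the control group and 57 over the libraries labelled knockout, a ratio of 59.7 (95% counting interval 10.3 to 2400). NAMPT, which encodes the main salvage enzyme, had 269 ± 3.41 and 279 ± 16.1 CPM in the groups (edgeR adjusted p = 0.37). The list did not pass camera (adjusted p = 0.7).

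Selenoprotein mRNAs that passed differed in both directions. A smaller share of them passed than the 45.4% of all tested genes. The same held for genes of selenocysteine synthesis and insertion. Of 21 tested selenoprotein genes other than SEPHS2, 5 rose and 3 fell (5 higher and 3 lower adjusted over the list alone). TXNRD1, the cytosolic thioredoxin reductase and also an NRF2 target, rose from 318 ± 6.28 to 434 ± 23.5 CPM (log2 fold change 0.45, SE 0.04, edgeR adjusted p = 3.46e-08). SELENOS rose by 0.20 and SELENON fell by 0.30 on the log2 scale. The largest fold change among those called was that of SELENOP, which is low here, from 0.382 ± 0.171 to 0.915 ± 0.0427 CPM (log2 fold change 1.26, SE 0.37, edgeR adjusted p = 0.00883). SELENOH and SELENOK also rose and GPX3 and SELENOW fell, but each of these calls, and that of SELENOP, was lost when 1 library was left out. The edgeR adjusted p became 0.0661 for SELENOH without knockout replicate 2, 0.0655 for SELENOK without control replicate 1 and 0.0524 for SELENOP without control replicate 2 (log2 fold change 0.94). It became 0.0697 for GPX3 without knockout replicate 3, and 0.0973, 0.109 and 0.0529 for SELENOW without control replicate 2, control replicate 3 or knockout replicate 1. With the length and GC trend removed, SELENOK (0.06, edgeR adjusted p = 0.375) and SELENOW (-0.12, edgeR adjusted p = 0.0812) lost their calls. TXNRD2 (0.35, edgeR adjusted p = 3.19e-04) and SELENOF (-0.16, edgeR adjusted p = 0.00118) gained one in that setting. GPX1 and GPX4, glutathione peroxidases, had log2 fold changes of -0.03 and 0.08, with SEs of 0.08 and 0.05 (edgeR adjusted p = 0.828 and 0.234). GPX4 gained a call without knockout replicate 1 (0.13, edgeR adjusted p = 0.0465), and TXNRD2 without knockout replicate 3 (0.22, edgeR adjusted p = 0.0175). Of 12 tested genes for selenocysteine synthesis and insertion, 3 rose and 1 fell (3 higher and 1 lower adjusted over the list alone), with SEPHS1 at 0.24, TRNAU1AP at 0.22 and the selenoprotein P receptor LRP8 at 0.30. The fall of SECISBP2 (-0.11, edgeR adjusted p = 0.0364) was lost when any library other than control replicate 2 was left out (adjusted p = 0.0573 to 0.122). Neither list passed camera (adjusted p = 0.232 and 0.334 in that order).

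Genes of cell division rose almost without exception among the fixed lists. Of 29 S phase genes 28 rose, and of 30 mitotic genes 30 rose (28 and 30 adjusted over the list alone), with median log2 fold changes of 0.62 and 0.50. PCNA, the sliding clamp of replication, rose from 142 ± 0.567 to 250.0 ± 9.86 CPM (log2 fold change 0.81, SE 0.04, edgeR adjusted p = 1.36e-12). RRM2, E2F1, ANLN, CDC20 and KIF11 rose by log2 fold changes of 0.72, 0.86, 0.64, 0.67 and 0.65. TYMS (1.59) and NDC80 (1.52) rose most among the named members, and both lie in the part of chromosome 18 whose genes were higher as a whole. Both lists passed camera (adjusted p = 1.01e-12 and 1.85e-13). They had adjusted p = 0.314 with an estimated correlation for S phase and adjusted p = 0.287 with an estimated correlation for mitosis.

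Several lists of redox and stress genes were higher. Of 25 NRF2 targets, 19 rose and 2 fell (20 higher and 2 lower adjusted over the list alone), and 1 fell without control replicate 1, control replicate 3 or knockout replicate 3. FTL, the ferritin light chain, rose from 587 ± 59.3 to 1283 ± 58.3 CPM (log2 fold change 1.13, SE 0.06, edgeR adjusted p = 8.55e-13). GCLM, which supports glutathione synthesis, PRDX1 and ABCC2 rose by 0.91, 0.73 and 0.90. Of 27 glutathione genes 14 rose and 3 fell (16 higher and 3 lower adjusted over the list alone), with the cystine transporter subunit SLC3A2 at 0.63. Of 33 ferroptosis genes 15 rose and 2 fell (15 higher and 2 lower adjusted over the list alone), and these include FTL and SLC3A2 again, with SAT1 lower at -0.62. These lists share members and passed camera (adjusted p = 6.18e-07, 0.0144 and 0.0113). NRF2 targets had adjusted p = 0.287 with an estimated correlation, glutathione genes adjusted p = 0.314 with an estimated correlation and ferroptosis genes adjusted p = 0.349 with an estimated correlation.

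Of 35 ATF4 targets of the integrated stress response, 18 rose and 4 fell (19 higher and 5 lower adjusted over the list alone), among them SLC7A5 (0.80), PHGDH (0.68) and DDIT4 (0.65). Of 23 serine and one-carbon genes 15 rose and 3 fell (15 higher and 3 lower adjusted over the list alone), with PSAT1 at 0.56. Of 15 heat shock genes 10 rose and none fell (11 higher adjusted over the list alone; 9 rose and 1 fell without knockout replicate 1), and HSP90AA1 rose from 1342 ± 18 to 2306 ± 219 CPM (log2 fold change 0.78, SE 0.05, edgeR adjusted p = 1.01e-10). Of 25 p53 targets 12 rose and 4 fell (13 higher and 4 lower adjusted over the list alone), with BAX and CDKN1A higher (0.72 and 0.63) and AEN and PMAIP1 lower (-0.62 and -0.57). Of 24 cholesterol genes 12 rose and 2 fell (12 higher and 2 lower adjusted over the list alone), including HMGCS1 (0.49) and IDI1 (0.47). All 5 lists passed camera, from adjusted p = 0.0011 for heat shock to 0.0187 for p53. The ATF4, serine and heat shock lists had adjusted p = 0.349 with an estimated correlation, and the p53 and cholesterol lists adjusted p = 0.314 with an estimated correlation.

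Nuclear-encoded respiratory chain subunits and ribosomal protein genes rose slightly where they passed the test, with few exceptions. Of 71 respiratory chain genes 46 rose and 2 fell (47 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 0.18 and NDUFB4 at 0.37, and 1 fell without control replicate 2 or knockout replicate 3. Of 73 ribosomal protein genes 34 rose and 1 fell (35 higher and 1 lower adjusted over the list alone), with a median of 0.12 and RPL38 at 0.28. With 1 library left out, 36 to 48 respiratory chain genes and 24 to 48 ribosomal protein genes rose. Both lists passed camera (adjusted p = 5.45e-07 and 4.01e-05). They had adjusted p = 0.468 with an estimated correlation for the respiratory chain and adjusted p = 0.642 with an estimated correlation for ribosomal proteins, and fry did not call the ribosomal list (adjusted p = 0.126).

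Inflammatory genes showed the lowest median among lists with at least 5 tested members. Of 25 NF-kB and cytokine genes 21 fell and 1 rose (1 higher and 21 lower adjusted over the list alone), with a median log2 fold change of -1.01. The chemokine CXCL8 fell from 229.8 ± 7.34 to 82.4 ± 4.49 CPM (log2 fold change -1.48, SE 0.05, edgeR adjusted p = 1.11e-15), and CCL2 fell from 9.35 ± 0.84 to 0.139 ± 0.0422 CPM (log2 fold change -6.07, SE 0.21, edgeR adjusted p = 4.30e-15). ICAM1, an adhesion molecule, fell by a log2 fold change of -1.46, and SOD2, a mitochondrial superoxide dismutase, from 131 ± 4.11 to 65.6 ± 1.14 CPM. The list passed camera (adjusted p = 1.08e-10) and had adjusted p = 0.185 with an estimated correlation.

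Of 44 collagen and matrix genes, 28 fell and 5 rose (6 higher and 28 lower adjusted over the list alone). Tenascin C (TNC) fell from 2696 ± 34.4 to 1089 ± 70.2 CPM (log2 fold change -1.31, SE 0.05, edgeR adjusted p = 5.10e-15). Fibronectin (FN1), COL6A2 and the collagenase MMP1 fell by -2.00, -1.03 and -4.37. Of 22 ERK output genes 14 fell and 3 rose (3 higher and 14 lower adjusted over the list alone), with SPRY4 at -0.95, HMGA2 at -0.94, EGR1 at -1.27 and SPRY2, on chromosome 13, at -0.88. Both lists passed camera (adjusted p = 5.45e-07 and 0.00173). The matrix list had adjusted p = 0.171 with an estimated correlation, and the ERK list adjusted p = 0.287 with an estimated correlation. Of 20 immediate early genes 10 fell and 3 rose (3 higher and 10 lower adjusted over the list alone), JUNB by -0.95 and IER3 by -0.69. Its camera call (adjusted p = 0.036, adjusted p = 0.396 with an estimated correlation) was lost without control replicate 1 (adjusted p = 0.069) or knockout replicate 3 (adjusted p = 0.0709). It was also lost with the replicate number as a block (camera adjusted p = 0.0848).

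Across the 35 lists tested, 18 passed camera with the preset correlation, 14 higher and 4 lower, and 1 of these was among the 6 primary lists. Splits of the 6 libraries that mix both labels gave 2 to 13 lists past camera and 0 changed genes. Such splits still hold part of the group difference. With an estimated correlation 0 lists passed, 5 were under an unadjusted p of 0.05, and fry called 26. Among the primary lists, fry called pentose phosphate, gluconeogenesis, selenocysteine synthesis and glycolysis genes (fry adjusted p = 4.22e-04, 3.84e-04, 0.00431 and 0.0236). It did not call selenoproteins or NAD genes (fry adjusted p = 0.126 and 0.106). Of other lists not past camera, it called dedifferentiated, metal, melanocyte, fibroblast, fatty acid and endothelial genes (fry adjusted p = 0.0013 to 0.0286).

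**Figure D2:**
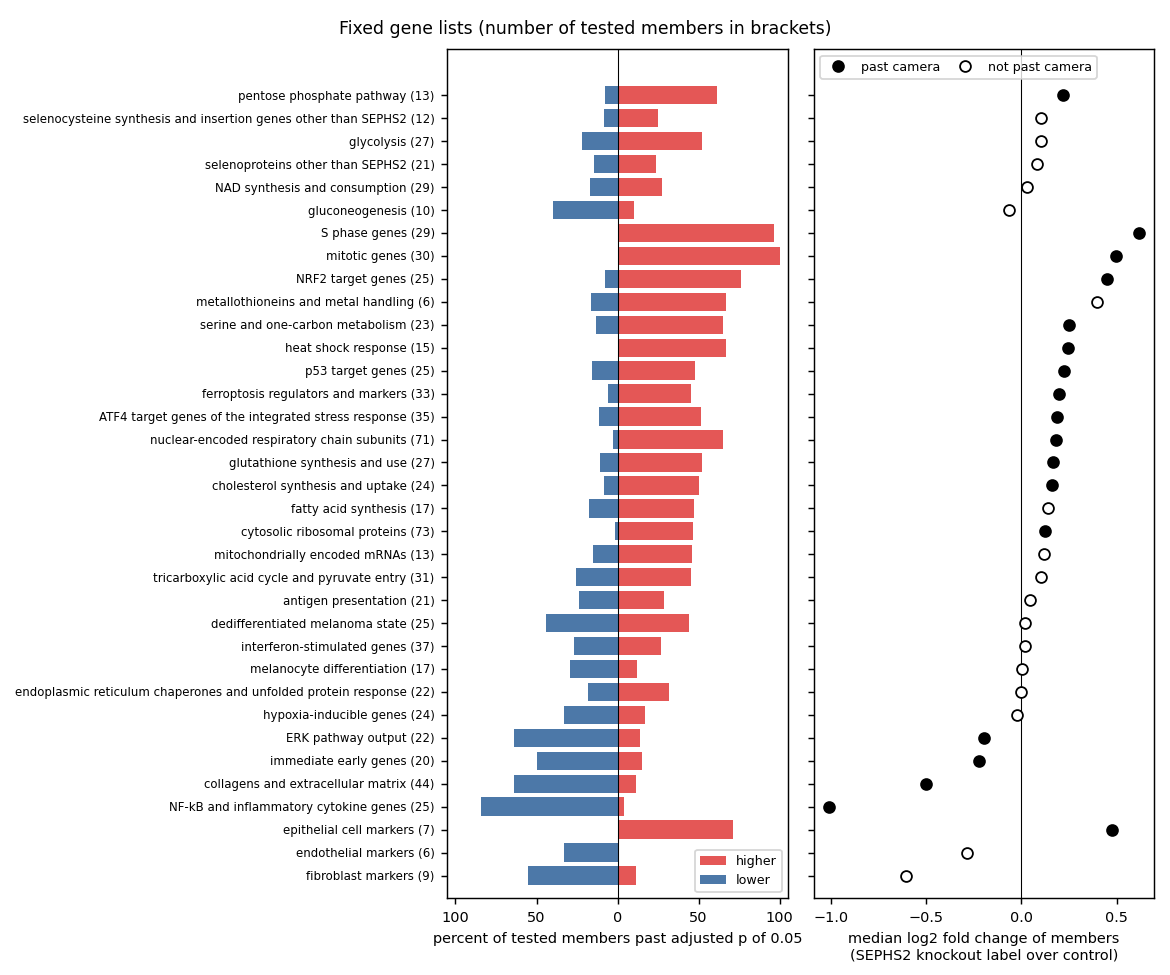
For each fixed gene list with at least 5 tested members, the percent of members past the edgeR threshold in each direction (left) and the median log2 fold change, libraries labelled SEPHS2 knockout over control (right). Filled points passed camera with the preset correlation, and none of them passed with an estimated correlation. NF-kB genes have the lowest median, -1.01, and S phase genes the highest, 0.62.

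Among genes that met the rule for single genes, the largest rise was in CCBE1, a secreted protein of lymphatic vessel growth, from 0.851 ± 0.195 to 16.5 ± 0.834 CPM (log2 fold change 4.28, SE 0.14, edgeR adjusted p = 1.11e-15). It was followed by ALPP (3.50) and KRT81 (2.89), both uncertain because close paralogs can share reads. ST6GALNAC5, CALB2, ABCA13, CLU, TM4SF18 and FHOD3 rose by log2 fold changes of 2.27 to 2.51. LNCAROD (2.37) is uncertain, since another symbol has identical counts. Of the largest falls under that rule, KCNJ8, a potassium channel subunit, UNC5D, a netrin receptor, ZNF727, RBM11 and ZNF239 had no reads in any library labelled knockout. With 3 reads over the group as the floor, they were nominally 182, 171, 102, 92.6 and 80.5-fold lower. The lower limits of the 95% counting intervals of the ratios, 147, 139, 82.3, 74.8 and 65, lie below these values. LINC01419, which the rule leaves out by its symbol and which is named after its values were seen, had 1174 reads over the control group and none in any library labelled knockout. TFAP2B, a transcription factor of the neural crest, fell from 5146 reads over the control group to 8, a ratio of 614 (95% counting interval 311 to 1423). SLC24A3, NDN and GFRA1 fell from 479, 673 and 333 reads to 2, 4 and 2, with ratios of 229 (62.9 to 1893), 161 (62.4 to 591) and 159 (43.7 to 1318).

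Markers of other cell types were mostly low and moved in both directions. Of 7 tested epithelial markers 5 rose (6 adjusted over the list alone; 3 without control replicate 1), among them KRT8 from 75 ± 2.3 to 104 ± 6.84 CPM (log2 fold change 0.48, SE 0.05, edgeR adjusted p = 7.76e-08) and KRT14 from 0.317 ± 0.0883 to 1.42 ± 0.401 CPM. That list passed camera (adjusted p = 0.0369, adjusted p = 0.314 with an estimated correlation), a call lost without control replicate 1, control replicate 2 or knockout replicate 3 (adjusted p = 0.122, 0.0635 and 0.0763). The call was also lost with the replicate number as a block (camera adjusted p = 0.0694). Of 9 fibroblast markers 5 fell and 1 rose (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.256), with PDGFRB at -0.86 and LUM at 0.76. Of 6 endothelial markers 2 fell (2 adjusted over the list alone; camera adjusted p = 0.304), with EGFL7 at -0.42 and TEK at -1.04. The call of TEK (edgeR adjusted p = 0.0314) was lost with DESeq2 (adjusted p = 0.0653) and when any library other than control replicate 1 was left out (adjusted p = 0.0529 to 0.166). Of 3 leukocyte markers 1, LYZ, rose (1.03; 1 adjusted over the list alone), and the 1 erythroid marker tested, HBG1, had a log2 fold change of -1.10, SE 0.65 (edgeR adjusted p = 0.184).

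Expression also differed by chromosome. Of 233 genes on chromosome 13 with at least 2 CPM, 185 fell and 7 rose, with a median log2 fold change of -0.41, and 90.1% lay below 0. In the first 15 Mb of chromosome 18, a limit chosen after the values were seen, 44 of 48 genes rose, with a median of 0.95. The 132 genes beyond 20 Mb of that chromosome had a median of 0.03, and the medians of all other chromosomes lay between -0.02 and 0.05. Against the mean of the control libraries, the 3 libraries labelled knockout had medians of -0.40, -0.43 and -0.40 on chromosome 13. They had 0.98, 0.95 and 0.95 in the first part of chromosome 18.

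**Figure D3:**
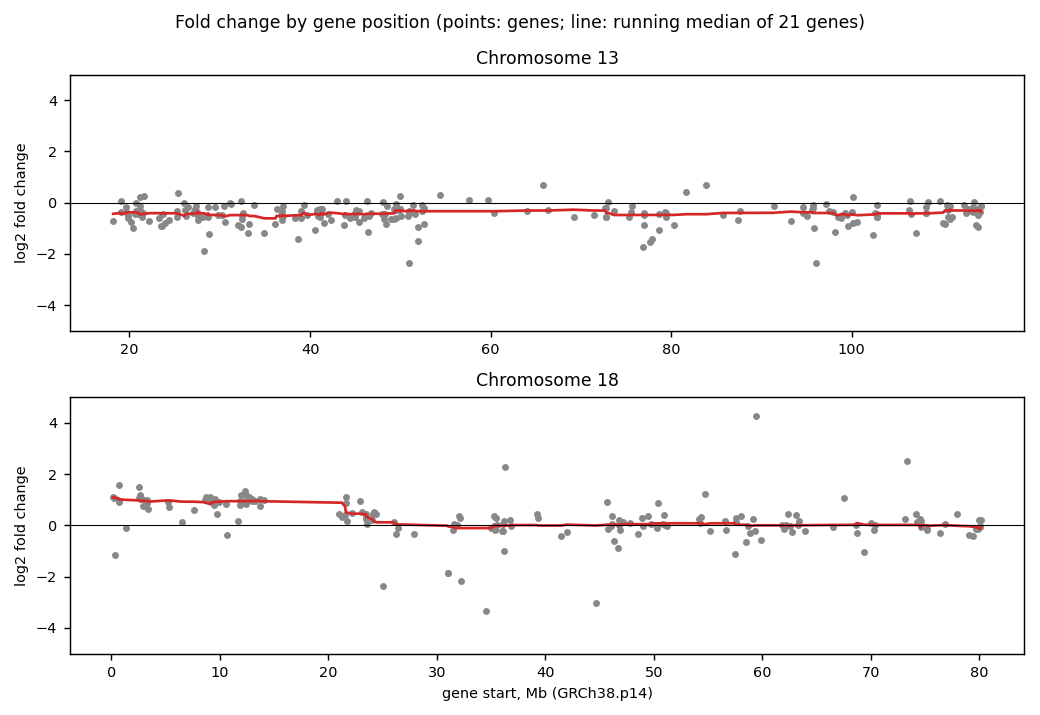
Log2 fold change, libraries labelled SEPHS2 knockout over control, of genes with at least 2 CPM against gene start in Mb on chromosomes 13 and 18, with points for genes and a line for the running median of 21 genes. The line lies below 0 along chromosome 13, and near 1 only in the first part of chromosome 18.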

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

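Leaving out chromosomes 13 and 18, keeping 1 of each set of genes with identical counts, and removing the length and GC trend were tests chosen only after the results were seen. Over all alternatives, the number of changed genes ran from 5863 (adjusted p under 0.01) to 7774, and from 6975 with DESeq2, where 1261 adjusted p-values are NA, to 7632 with limma-voom. Leaving out 1 library gave 6339 to 7411 changed genes, 920 to 1220 with at least a 2-fold change, and 16 to 18 lists past camera. Over the alternatives the log2 fold change of SEPHS2 was 0.10 to 0.17 and that of PCK1 -7.80 to -7.43, both past the threshold in each. Requiring at least 1 CPM in 3 libraries tested 14155 genes and gave 7232 changed genes, against 7673. It gave 623 with at least a 2-fold change, against 1170, so many of the 2-fold changes lay in low genes that this filter removes. With an estimated correlation 0 lists passed, against 18, and the cause was not tested. Removing the length and GC trend changed the sign of SELENOF (-0.16), PFKL (0.0483) and NADSYN1 (0.16), and the cause was not tested. It gave 7637 changed genes, 54.2% of them higher against 48.5%, and 15 of 6430 shared calls had the opposite sign. Without chromosomes 13 and 18, 7288 genes changed. That setting drops only the genes on these chromosomes, so it cannot remove other differences between the cells of the groups. Of the alternatives for named genes, 3911 kept direction and side of the threshold, 84 lost the threshold, 12 gained it and 3 changed sign. For lists these numbers were 519, 27 and 12, with no change of sign.

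The replicate numbers are shared across groups, but same-numbered libraries did not deviate together: the correlations of their deviations were 0.01, -0.09 and -0.25, and not every library correlated best with its own number. With the replicate block, 7774 genes changed, 7548 of them shared with the fit without it, and 16 lists passed. No call of a named gene changed under the block. The list calls lost under the block were immediate early genes (adjusted p = 0.0848) and epithelial markers (adjusted p = 0.0694). Depth limits small changes of low genes: of simulated 1.2-fold changes, 3.08%, 60.5% and 98.6% were recovered in the lowest, middle and highest expression class, and 1.54%, 47.6% and 93.7% at 50% of the depth. This simulation changed a smaller share of genes than was called in the data, so these rates may understate recovery.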

Other observations

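The tests of copy number, of depth, of a founding cell, of scaling and of genes of similar abundance were chosen only after the results were seen. Other fixed lists moved in both directions in the libraries labelled knockout, whose SEPHS2 mRNA was not lower. Of 37 interferon-stimulated genes 10 rose and 10 fell (11 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.869), with BST2 at -1.27, IFITM1 at -1.49 and IFI44 at 0.48. Of 21 antigen presentation genes 6 rose and 5 fell (6 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.727), with TAPBP at -0.34 and HLA-DRA at 0.33. Of 25 genes of the dedifferentiated melanoma state 11 rose and 11 fell (11 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.616), and the nerve growth factor receptor NGFR rose from 6.12 ± 0.342 to 24.1 ± 3.61 CPM while TGFBI fell by -1.12. Of 17 melanocyte genes 2 rose and 5 fell (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.718), 3 lower without control replicate 2, with GPNMB at 0.34, APOE at -1.50 and EDNRB, on chromosome 13, at -1.41. Of 24 hypoxia genes 4 rose and 8 fell (4 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.584), 5 lower without knockout replicate 1, with STC1 at -1.19. Of 22 unfolded protein response genes 7 rose and 4 fell (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.823), 4 higher without control replicate 1, with ERN1 at -0.58.

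Of 31 tricarboxylic acid cycle genes 14 rose and 8 fell (14 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.392), with IDH1 at 0.51 and PDK3, which inhibits pyruvate entry, at -0.69. Of 13 mitochondrially encoded mRNAs 6 rose and 2 fell (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.197), with ND3 at 0.40 and COX1 at -0.21. Of 17 fatty acid synthesis genes 8 rose and 3 fell (8 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.105), with ME1 at 0.52 and FADS2 at 0.60, and this list passed once the length and GC trend was removed (adjusted p = 0.0198). Of 6 metal handling genes 4 rose and 1 fell (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0718), with MT2A at 0.40, and this list passed with no filter on low counts (adjusted p = 0.0464). Among abundant mRNAs, EEF1A1 (0.19), HNRNPA2B1 (0.41) and NPM1 (0.34) rose, while SERPINE2 fell from 8747 ± 159.7 to 6172 ± 353 CPM and GNAS from 2795 ± 109 to 1806 ± 84.7 CPM (edgeR adjusted p = 6.80e-09 and 2.34e-10).

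The first pattern is the lower expression of chromosome 13 and the higher expression of the first part of chromosome 18. A gene length or GC trend as the whole cause is argued against, because the chromosome 13 median was -0.44 with that trend removed, and that of the first part of chromosome 18 0.99. Random placement is argued against too, since 0 of 1000 shuffles of gene positions gave a chromosome median as far from 0, the largest being 0.10. A different copy number of these regions in the cells of the 2 groups is a candidate explanation. Of chromosome 13 genes 90.1% lay below 0, with medians of -0.46, -0.41 and -0.40 in its low, middle and high expression classes. Copy number would give this, but so would any shift of the whole chromosome. The values were also known before the test was chosen, so they do not decide it. This test covers chromosome 13 only, and DNA was not analysed here. Any effect of SEPHS2 loss on these regions stays open and untested.

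The second pattern is a set of 59 genes with at least 60 reads over the control libraries and at most 6 over those labelled knockout, PCK1 among them, against 2 the other way, LINC02387 and VN1R60P, named after their values were seen. Lower depth is argued against, since the libraries labelled knockout held 96.3% of the control reads. Loss of the surrounding region is argued against as well, because the nearest tested neighbours had a median log2 fold change of 0.0172 (SD 0.25) and 0 of 58 lay at or below -1. A founding cell or subpopulation that did not express these genes cannot be told apart from an effect of SEPHS2 loss. That 50 of them had at most 3 reads in every library labelled knockout supports neither, because choosing genes with at most 6 reads over the group nearly forces it. The labels name 1 knockout group and no separate lines, which keeps both open.

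The third pattern is the small rise of ribosomal protein and respiratory chain mRNAs. The SEs given for it are over list members, treated as independent, and do not measure the spread between libraries. A length or GC trend as the whole cause is argued against, since the smaller of the list medians was 0.10 with that trend removed (SE 0.02). The median of all tested genes was then 0.02, against 0.01 before, so the excess over other genes was less than 0.10. RLE and upper-quartile factors moved these medians by at most 0.01, too little to test scaling. A factor per library moves every gene alike, and scaling as the whole cause is argued against because the smaller list median exceeded the median of the 16766 other tested genes by 0.12 (SE 0.01). A rise shared by genes of similar abundance is argued against for the respiratory chain list, whose median exceeded that of the 50 genes nearest in abundance to each member by 0.17 (SE 0.03). For the ribosomal protein list that difference was 0.0513 (SE 0.01), less than its median of 0.12, since genes of similar abundance rose too (median 0.07), so a shared rise stays open for it. Neither list passed with an estimated correlation, so whether the genes of each list moved beyond their shared variation stays open, as does an untested effect of SEPHS2 loss.

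For the counts of changed genes, higher genes, lower genes and genes with at least a 2-fold change, 1 of the 10 splits of the 6 libraries, the real one, gave as many. The real values were 7673, 3723, 3950 and 1170, and the highest of the other 9 splits was 0 in each case by edgeR. At an unadjusted p under 0.05 the other splits gave 123 to 370 genes, against 8653, and no other tool was run on the splits. Each of the other 9 splits put libraries of both labels on both sides, so the group difference added to the spread within each side. That leaves few gene calls by construction, so these splits are no baseline for chance. For lists past camera the real split gave 18 and the other splits 2 to 13, again 1 of 10. Lists thus passed camera where 0 genes changed. The other splits still hold part of the group difference, so they are no baseline for lists either. With 10 splits no share under 0.05 can be reached. Short runs of genes at ZNF431 on chromosome 19 and at DDX3X on chromosome X also passed the largest window median of 200 shuffles, 0.27, with medians of 0.29 and -0.29, and both genes were picked after their values were seen.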
